A study of Homo sapiens with 21 samples.

How the data were processed

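Total RNA from RKO cells was extracted with TRIzol and libraries were made with a TruSeq Stranded mRNA kit, per the labels' protocols. The labels give 21 libraries in 5 groups: non-targeting siRNA (4), mock transfection (5) and siRNAs named for Myc, SNTA1 and KCNK1 (4 each). Per the labels' design text at least 4 replicates of transfected cells were used, with a library for each. Which replicates were cultured, transfected or sequenced together is not given in the sources used here, nor are the siRNA sequences.

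The authors aligned reads to hg19 with TopHat2 2.0.10 and computed FPKM values with Cufflinks, per the submitters' processing notes, and deposited them in a single table with a column for each library. The deposited score columns are signed folds, each the ratio of 2 group mean FPKM values, with a minus sign where the siRNA group is lower; this was checked by recomputing them. The deposited p-values were recovered by an unequal-variance t-test on FPKM, and the deposited q-values by a Benjamini-Hochberg adjustment over all loci of the table. With those q-values the authors' table has 4125 loci below 0.05 for Myc, 3271 for SNTA1 and 3085 for KCNK1 siRNA against non-targeting siRNA. The authors' scores, p-values and q-values were not used for any result except as the alternative named below. For every locus of the deposited table, a group's libraries were either all at 1 FPKM or more or all below it, and 2 loci were below 1 FPKM in each group. The filter that decided which loci the authors listed is not given in the sources used here, so genes missing from the table are not taken as absent from the cells. The table holds no read counts and no library sizes, so depth per sample and the counting precision of each FPKM are unknown.

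FPKM values were taken as deposited, and log2(FPKM + 1) was used for tests. Loci with at least 1 FPKM in at least 4 samples were tested, which left 10713. The table has 28 loci that share 14 symbols, and these were kept apart by position. All 5 groups were compared in a single fit of the 21 libraries with a mean per group, with limma 3.58.1 in R 4.3.3 and a trend of variance on expression. Calls are those with a Benjamini-Hochberg adjusted p below 0.05. The comparisons were each siRNA against non-targeting siRNA, non-targeting siRNA against mock, and the 3 pairs of siRNAs. For single named genes an exact two-sided permutation test on the mean of log2(FPKM + 1) is also given where stated. Spread is the SD between libraries, and errors of log2 changes are the SE of the fit.

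Gene lists were tested with camera of limma, with its preset correlation between genes of 0.01 and again with a correlation estimated for each list, adjusted over the lists by Benjamini-Hochberg. Of 28 lists 26 could be tested. The lists of other cell types (fibroblast, blood and endothelium, 15 genes) and of mitochondrially encoded genes (13 genes) had 0 measured members. Members absent from the table were many in some lists, with 4 of 18 epithelial, 5 of 12 mesenchymal, 8 of 19 NF-kB, 25 of 37 interferon, 6 of 17 dystrophin complex, 3 of 12 tandem-pore channel and 11 of 20 histone genes measured. The histone list holds replication-dependent genes, whose transcripts are poor in poly(A). Some genes stand in more than 1 list, as CDKN1A does among p53 targets and MYC-repressed genes. In 16 of 104 list tests the median or mean change of the list had another sign than the test, and 0 of these were called.

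The groups, comparisons, tests, thresholds, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule the text names MYC, SNTA1 and KCNK1 throughout. For each siRNA against non-targeting siRNA it names genes from the 10 largest changes each way among calls with a group mean of at least 5 FPKM and no overlap between the groups, and from the 5 largest in the other comparisons. It also names up to 4 called members per list with the largest change, up to 5 genes each way called in the same direction with all 3 siRNAs, and, for Myc siRNA, all measured BCL2 family members and EGR1. BCL2L1, CDKN1A, EGR1 and GDF15 are repeated in other comparisons for contrast.

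The alternatives fixed in that way were quantile normalization, median ratio scaling, a pseudocount of 0.1, no filter and a filter at 5 FPKM, a robust variance model, only the 2 groups compared, a replicate block, mock in place of non-targeting siRNA, an absolute log2 change of at least 1, an estimated correlation, controls split 2 and 2, and leaving out each library in turn. Alternatives added later were a spline correction of each library on GC and transcript length, array weights, scaling to the total outside short RNA, leaving Myc siRNA replicate 4 out of the common fit, and the authors' deposited q-values. Short RNA here means the 65 loci shorter than 500 bases named as small nucleolar RNA, microRNA or other short RNA.

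GC, transcript length and 3' UTRs came from GENCODE release 44 lifted to GRCh37, using the canonical transcript. Of the loci, 9457 matched by symbol, 954 by an older symbol and 304 not at all, and 97.2% had GC and length. For the search of 3' UTRs, each of 16140 heptamers found in at least 50 genes was tested for association with the log2 changes of 9997 genes, after removing trends with UTR length, base composition and expression. The values were scaled to z, and 100 shuffles of the genes gave the size that chance reaches. Loading and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

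The steps were tested on simulated data, with normal noise drawn independently for each gene at its SD within groups. In 5 rounds with 200 of 10713 genes changed between 4 and 4 libraries, 78% of changes of 0.5 and 99.2% of changes of 1 on the log2 scale were recovered, and 4.73% of calls were false. A list of 27 genes raised together by 0.3 was called in 100% of rounds at the preset correlation. The simulated genes were not correlated, so these rates do not cover genes or lists whose members vary together. No library was left out. Genes specific to X inactivation or the Y chromosome are not reported, and the robust variance model was not run for gene lists.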

Results

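Poly(A) RNA sequencing was carried out on 21 libraries of RKO cells, a human colon carcinoma line that carries wild-type TP53. The cells had been transfected with non-targeting siRNAs (n = 4), with siRNAs named for MYC (n = 4), SNTA1 (n = 4) or KCNK1 (n = 4), or mock-transfected (n = 5). An siRNA is a short double-stranded RNA that directs the degradation of matching transcripts. MYC encodes a transcription factor that drives growth and ribosome production. SNTA1 encodes alpha-syntrophin, an adaptor of the dystrophin complex at the plasma membrane, and KCNK1 encodes a tandem-pore potassium channel. The title of the series names MYC as a determinant of what becomes of cells in mitosis. The comparisons address which transcripts changed with each siRNA. No drug treatment is named in the labels of these samples. Expression was measured as FPKM, and 10713 loci that reached at least 1 FPKM in at least 4 libraries were tested. A library had between 10641 and 10707 loci at 1 FPKM or more, and the median FPKM per library was 15.9 to 17.4. The table holds FPKM and no read counts, so the depth behind each value is unknown. One locus, MIR4461, took 31.4% to 53.1% of the summed FPKM of a library. The lowest share was in replicate 4 of the Myc siRNA and the highest in replicate 2 of the SNTA1 siRNA. FPKM is divided by length, so for a short locus this is not a share of reads, and its FPKM is uncertain. The labels do not say whether replicates came from separate cultures or days, so p-values measure only the spread between these samples, which may be technical.

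Each siRNA group had less of the transcript it was named for than the non-targeting controls. MYC (hg19 chromosome 8, 128748314 to 128753680, 3 exons) stood at 154 ± 9.70 FPKM (SD, n = 4) with Myc siRNA, between 143.8 and 166.8 in the libraries, against 219 ± 8.31 FPKM (SD, n = 4) with non-targeting siRNA, between 206.6 and 225.1. That is 70.4% of the control level and a log2 change of -0.50 ± 0.07 (SE; limma adjusted p = 1.7e-06). SNTA1 (hg19 chromosome 20, 31995762 to 32031698, 8 exons, minus strand) fell from 4.36 ± 0.601 to 0.566 ± 0.0964 FPKM (SD, n = 4 each) with its own siRNA, with libraries at 0.474 to 0.658 FPKM against 3.81 to 5.19 FPKM. KCNK1 (hg19 chromosome 1, 233749749 to 233808258, 3 exons) fell from 12.3 ± 0.363 to 2.96 ± 0.788 FPKM (SD, n = 4 each), with libraries at 1.89 to 3.74 FPKM against 12 to 12.7 FPKM. The log2 changes were -1.77 ± 0.11 for SNTA1 and -1.77 ± 0.11 for KCNK1 (SE; limma adjusted p = 1.5e-10 and 2.9e-10), on the log2(FPKM + 1) scale, which understates the change of a low gene such as SNTA1. In each of these 3 comparisons no library of one group overlapped the other group, and the exact two-sided permutation p of 0.0286 is the smallest that 4 against 4 can give. Mock-transfected cells had 201 ± 11.1 FPKM of MYC, 4.60 ± 0.575 of SNTA1 and 12 ± 1.16 of KCNK1 (SD, n = 5).

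The other siRNAs also moved the targeted genes. MYC was higher with SNTA1 siRNA, at 284 ± 23.3 FPKM (SD, n = 4; log2 change 0.37 ± 0.07, limma adjusted p = 0.00026), and lower with KCNK1 siRNA, at 169 ± 11.9 FPKM (SD, n = 4; log2 change -0.37 ± 0.07, limma adjusted p = 0.00037). SNTA1 rose to 7.59 ± 1.36 FPKM with Myc siRNA (SD, n = 4; log2 change 0.67 ± 0.11, limma adjusted p = 1.4e-05). It was 5.90 ± 0.582 FPKM with KCNK1 siRNA (SD, n = 4; log2 change 0.37 ± 0.11, limma adjusted p = 0.014). That last call was lost without non-targeting replicate 1 (limma adjusted p = 0.052) and without KCNK1 siRNA replicate 4 (0.056), with a range of 0.0040 to 0.056 over all alternatives. KCNK1 itself did not pass the test with Myc siRNA (14.5 ± 0.822 FPKM, limma adjusted p = 0.084) or with SNTA1 siRNA (13.6 ± 0.923 FPKM, limma adjusted p = 0.39). With Myc siRNA KCNK1 passed, as higher, with only the 2 groups in the fit (limma adjusted p = 0.022), with mock in place of non-targeting siRNA (0.035) and with correction for GC and length (0.017), with a range of 0.017 to 0.28 over all alternatives.

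**Figure D1:**
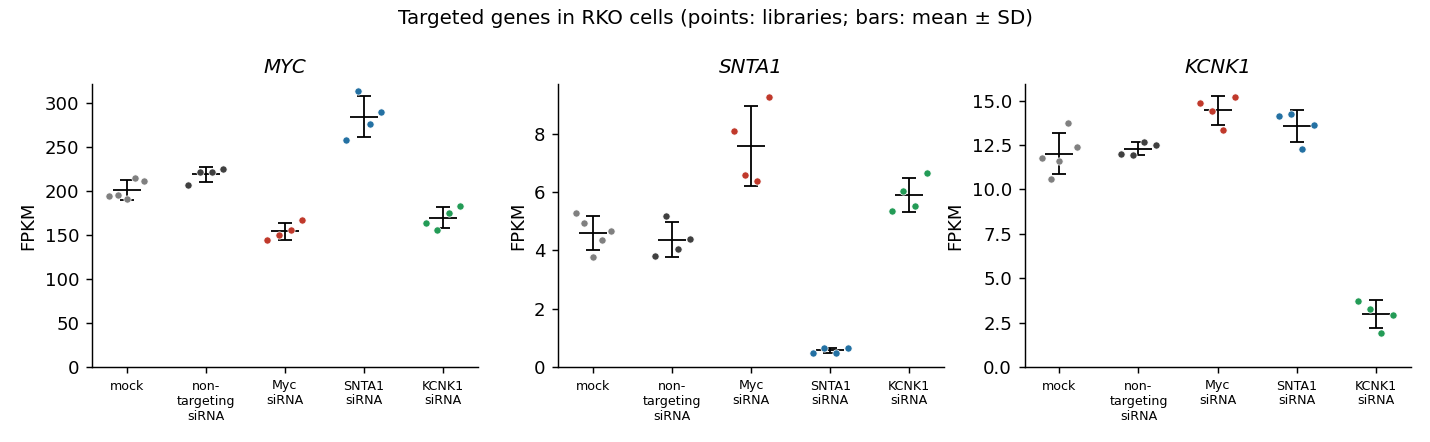
FPKM (vertical axis) of MYC, SNTA1 and KCNK1 in each library, by transfection group on the horizontal axis; points are libraries, and bars give the mean ± SD of 4 libraries, or 5 for mock. Each gene was lower with its own siRNA than in any non-targeting library, and MYC was also lower with KCNK1 siRNA and higher with SNTA1 siRNA.

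With Myc siRNA the genes of ribosome production and biosynthesis were lower. Of the 41 measured ribosome biogenesis genes, 40 fell and 0 rose. Among them were DDX21, an RNA helicase of the nucleolus (163 ± 10.7 to 55.7 ± 19.7 FPKM, SD, n = 4 each), NOLC1 (96.1 ± 1.81 to 34.6 ± 5.24), LYAR (84.0 ± 4.86 to 30.9 ± 5.33) and WDR12 (44.8 ± 0.963 to 16.4 ± 3.20). Their camera adjusted p was 3.8e-20, and the adjusted p = 0.077 with an estimated correlation. Of 37 classical MYC-activated genes, 32 fell and 0 rose. They were led by LDHA, which makes lactate at the end of glycolysis (496 ± 3.27 to 165 ± 36.2 FPKM), and the mitochondrial chaperone HSPD1 (768 ± 24.5 to 276 ± 40.6), with a camera adjusted p of 1.0e-13 and an adjusted p = 0.093 with an estimated correlation. Of 24 genes of nucleotide and folate synthesis, 22 fell and 0 rose, including MTHFD2 (121 ± 2.44 to 50.9 ± 8.99 FPKM), PFAS, MTHFD1L and PAICS, with a camera adjusted p of 2.9e-11 and an adjusted p = 0.077 with an estimated correlation. In the list of mitosis and the spindle checkpoint 29 of 36 genes fell and 2 rose. CCNB1, the cyclin that drives entry into mitosis, went from 187 ± 7.16 to 84.6 ± 9.79 FPKM, the mitotic kinase PLK1 from 115 ± 7.38 to 53.9 ± 7.20 and the checkpoint kinase BUB1B from 65.8 ± 2.23 to 32.8 ± 7.72 (camera adjusted p = 2.5e-08; adjusted p = 0.24 with an estimated correlation).

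Other groups were higher with Myc siRNA. Of 27 genes of lysosomes and autophagy, 24 rose and 0 fell. The cholesterol carrier NPC2 stood at 226 ± 71.7 against 83.3 ± 10.9 FPKM (SD, n = 4 each), WIPI1 at 22.1 ± 2.16 against 8.17 ± 0.553 and GBA at 56.4 ± 2.25 against 27.5 ± 2.52 (camera adjusted p = 3.6e-08; adjusted p = 0.11 with an estimated correlation). Of 25 measured interferon response genes, 19 rose and 3 fell. The risers included IFI6 (17.8 ± 7.65 against 3.97 ± 0.583 FPKM) and STAT2 (28.2 ± 3.10 against 10.8 ± 0.682), with a camera adjusted p of 0.00078 and an adjusted p = 0.093 with an estimated correlation. Of 13 measured genes reported as MYC-repressed, 10 rose and 1 fell. NDRG1 (37.7 ± 3.00 against 10.4 ± 0.735 FPKM) and GADD45B (31 ± 7.12 against 11 ± 0.462) led them, with a camera adjusted p of 0.0041 and an adjusted p = 0.11 with an estimated correlation. Of 24 measured immediate early genes, 16 rose, among them CTGF, CYR61 and DUSP6, and 5 fell, EGR1 the most (camera adjusted p = 0.045; adjusted p = 0.27 with an estimated correlation). This call was lost without non-targeting replicate 2 (camera adjusted p = 0.055), Myc siRNA replicate 1 (0.054) or Myc siRNA replicate 4 (0.090), and with correction for GC and length (0.088), with a range of 0.028 to 0.38 over all alternatives. The median of this list was 0.43 with the correction and 0.49 before it. The genes with the largest rises were AHNAK2 (12.2 ± 3.57 against 0.451 ± 0.0341 FPKM), the membrane scaffold CAV1 (37.3 ± 3.27 against 4.71 ± 0.293) and the urokinase gene PLAU (177 ± 6.24 against 26.0 ± 1.58). KLF2, C19orf33, ANXA1, TMSB4X, ITGAX, KCNN4 and MVP followed, at log2 changes of 2.58 to 2.37.

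Among the 10 largest falls with Myc siRNA were those of GPI, a glycolytic enzyme (27.5 ± 7.41 against 173 ± 4.25 FPKM, SD, n = 4 each), and SLC7A5, a transporter of large neutral amino acids (16.3 ± 4.18 against 86.3 ± 2.66). The others were C15orf63, GAL, POLR3G, MIR17HG, SLC7A2 and 3 small nucleolar RNAs, SNORD99, SNORA3 and SNORD102, at log2 changes of -2.39 to -1.77. Such RNAs lie within other genes and their FPKM is uncertain where reads are shared. Of 31 genes of the G1/S transition and DNA replication, 19 fell, CCNA2 the most, and 3 rose, including CCND1 and CCNE2 (camera adjusted p = 0.0018; adjusted p = 0.27 with an estimated correlation). Of 20 glycolysis genes, 12 fell and 5 rose (camera adjusted p = 0.025; adjusted p = 0.45 with an estimated correlation). This call was lost with quantile normalization, at 0.093 and a median of -0.24 in place of -0.27, with a range of 0.018 to 0.45 over all alternatives. Of 50 cytosolic ribosomal protein genes, 11 fell, RPS24 the most, and 0 rose (camera adjusted p = 0.017; adjusted p = 0.75 with an estimated correlation). The call of this list was lost without Myc siRNA replicate 1 (camera adjusted p = 0.10), replicate 2 (0.067) or replicate 3 (0.10), with a range of 5.7e-07 to 0.75 over all alternatives, and the medians were -0.13, -0.15 and -0.12 in place of -0.19.

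Among the BCL2 family, which sets the threshold of mitochondrial cell death, Myc siRNA moved members of both kinds. BCL2L1, which encodes the anti-apoptotic BCL-XL, rose from 86.9 ± 1.98 to 189 ± 12.8 FPKM (SD, n = 4 each; log2 change 1.11 ± 0.05, limma adjusted p = 1.1e-12), and BCL2A1 rose from 74.1 ± 7.85 to 116 ± 22.2 FPKM (limma adjusted p = 9.1e-05). The pro-apoptotic PMAIP1 (10.7 ± 1.43 to 5.88 ± 1.31 FPKM) and BID (38.9 ± 1.40 to 28.0 ± 4.99 FPKM) fell, with limma adjusted p = 2.7e-05 and 4.9e-05. The pro-apoptotic BBC3 (7.32 ± 0.630 to 12.1 ± 3.29 FPKM), BAK1 (49.3 ± 0.805 to 75.5 ± 6.29), BAD (36.4 ± 2.56 to 52.3 ± 15.4) and BAX (191 ± 13.6 to 244 ± 46.9) rose, with limma adjusted p of 0.00017, 3.7e-08, 0.0036 and 0.0069. MCL1 fell from 338 ± 10 to 293 ± 16 FPKM (log2 change -0.20 ± 0.07, limma adjusted p = 0.011), a call lost with quantile normalization (0.20) and with scaling to the total outside short RNA (0.053), its range being 0.0019 to 0.20. BCL2 (3.36 ± 0.950 against 4.14 ± 0.564 FPKM, limma adjusted p = 0.11) and BOK (20.7 ± 3.81 against 21.3 ± 0.855, limma adjusted p = 0.64) did not pass the test. BCL2 passed it, as lower, without Myc siRNA replicate 3 (limma adjusted p = 0.042) and with quantile normalization (0.0041), with a range of 0.0041 to 0.49 over all alternatives. BOK passed it, also as lower, with correction for GC and length (limma adjusted p = 0.0014) and with libraries weighted by quality (0.036), with a range of 0.0014 to 0.97. BCL2L11, which encodes BIM, was 3.04 ± 0.376 against 3.61 ± 0.310 FPKM (limma adjusted p = 0.026), BIK 4.47 ± 1.73 against 2.90 ± 0.202 (0.026) and BCL2L2 20.3 ± 1.13 against 18.3 ± 0.522 (0.042). These 3 calls were lost with only the 2 groups in the fit (limma adjusted p = 0.11, 0.073 and 0.10), in other settings and without single libraries. For BCL2L11 the libraries were non-targeting replicates 1 and 3 and Myc siRNA replicate 2 (limma adjusted p from 0.00029 to 0.11 over all alternatives). For BIK they were non-targeting replicates 2 and 3 and Myc siRNA replicates 1 and 4 (0.0049 to 0.20), and for BCL2L2 non-targeting replicates 2, 3 and 4 and Myc siRNA replicates 2 and 3 (0.0034 to 0.22). As a list, neither the 9 measured pro-apoptotic members (5 higher, 3 lower, camera adjusted p = 0.76) nor the 5 anti-apoptotic ones (3 higher, 1 lower, camera adjusted p = 0.46) passed the test. EGR1, an immediate early transcription factor, fell from 35.4 ± 3.44 to 13.6 ± 0.963 FPKM (SD, n = 4 each; log2 change -1.32 ± 0.09, limma adjusted p = 2.7e-10).

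In all, limma called 6617 of 10713 genes between Myc and non-targeting siRNA (Benjamini-Hochberg), 3639 higher and 2978 lower. Of these, 535 had a log2(FPKM + 1) change of at least 1 in size, 361 higher and 174 lower. Low genes can miss that bar at a 2-fold change of FPKM. The share of higher genes among all calls was 55.0%, but 48.3% with quantile normalization and 49.0% with median ratio scaling. Whether more genes rose than fell therefore depended on the scaling. In 50.9% of loci all 4 libraries of one group lay above all 4 of the other, against the 2.86% that chance gives. Of the 26 lists tested, camera called 11, and 0 of these with an estimated correlation. The 15 lists not called had camera adjusted p from 0.24 to 0.87. Death and growth lists among them were p53 targets (13 of 27 higher, 3 lower), death receptors, caspases and IAPs (12 of 21 higher, 3 lower), hypoxia response (7 of 11 higher, 3 lower), the MYC network (2 of 10 higher, 6 lower) and both BCL2 lists. Metabolic and stress lists were cholesterol and fatty acid synthesis (10 of 23 higher, 8 lower), unfolded protein response (5 of 19 higher, 7 lower), and NF-kB genes (1 of 8 higher, 2 lower). The rest were the dystrophin complex (3 of 6 higher, 0 lower), histones (3 of 11 higher, 1 lower), RNA interference genes (1 of 13 higher, 4 lower), tandem-pore channels (1 of 3 higher, 1 lower), epithelial markers (1 of 4 higher, 3 lower) and mesenchymal markers (2 of 5 higher, 1 lower). Counts adjusted over the list alone were equal to these for each list, except ribosomal proteins (8 lower), glycolysis (13 lower) and death receptors (13 higher). Replicate 4 of the Myc siRNA stood apart from the other 3 Myc libraries, its deviation having an SD of 0.471 on the log2 scale against 0.203 to 0.216 for the others, and without it limma called 7385 genes.

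With SNTA1 siRNA p53 targets were higher and genes of mitosis lower. Of 27 measured p53 targets, 24 rose and 0 fell. GDF15, a stress-induced cytokine, went from 7.40 ± 1.41 to 47.7 ± 7.23 FPKM (SD, n = 4 each; log2 change 2.54 ± 0.14, limma adjusted p = 3.4e-11). The CDK inhibitor CDKN1A went from 94.8 ± 6.89 to 309 ± 26.7 FPKM (log2 change 1.69 ± 0.09, limma adjusted p = 1.5e-11), and BTG2 from 10.1 ± 0.837 to 41.1 ± 5.05 FPKM. The camera adjusted p of the list was 6.7e-25, and it stayed below 0.05 with an estimated correlation, at an adjusted p = 1.7e-06. Of 36 genes of mitosis and the spindle checkpoint, 33 fell and 1 rose. BUB1B went from 65.8 ± 2.23 to 22.2 ± 2.70 FPKM, PLK1 from 115 ± 7.38 to 50.9 ± 10.6, NUF2 from 38.6 ± 1.09 to 17.4 ± 4.08 and AURKA from 99.6 ± 4.56 to 46.6 ± 8.27 (SD, n = 4 each; camera adjusted p = 8.4e-19; adjusted p = 0.032 with an estimated correlation). Of 31 genes of the G1/S transition and DNA replication, 23 fell and 2 rose. The replication factor GINS1 (31.3 ± 1.54 to 10.2 ± 1.16 FPKM) and CDK2 (79.3 ± 1.30 to 32.7 ± 3.66) fell most, with a camera adjusted p of 6.2e-11 and an adjusted p = 0.014 with an estimated correlation. With correction for GC and length the mitosis list no longer passed, at an adjusted p = 0.077 with an estimated correlation, nor did the G1/S list, at an adjusted p = 0.054 with an estimated correlation. Their medians were then -0.70 and -0.34, against -0.74 and -0.37 without the correction, and both passed at the preset correlation. Without Myc siRNA replicate 4 in the fit the mitosis list was at an adjusted p = 0.062 with an estimated correlation. Over all alternatives the adjusted p ran from 7.5e-21 to 0.077 for the mitosis list and from 3.1e-11 to 0.054 for the G1/S list.

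With SNTA1 siRNA, NF-kB and immediate early genes were higher as well. Of 8 measured NF-kB and cytokine genes, 7 rose and 0 fell. They included the apoptosis inhibitor BIRC3 (2.41 ± 0.443 to 7.74 ± 1.77 FPKM, SD, n = 4 each), NFKBIA (20.7 ± 1.37 to 47.7 ± 3.67) and ICAM1 (21.9 ± 0.907 to 46.9 ± 3.36), with a camera adjusted p of 6.0e-11 and an adjusted p = 0.00026 with an estimated correlation. Of 24 measured immediate early genes, 13 rose, IER3 and DUSP6 the most, and 2 fell (camera adjusted p = 2.4e-07; adjusted p = 0.0068 with an estimated correlation). Of 11 measured replication-dependent histone genes, whose transcripts are poor in poly(A), 6 rose and 0 fell (camera adjusted p = 7.6e-05; adjusted p = 0.0499 with an estimated correlation). Poly(A) libraries capture only a part of such transcripts, so a change of their total level was not measured. The histone list no longer passed with correction for GC and length, at an adjusted p = 0.23 with an estimated correlation, or without Myc siRNA replicate 4, at an adjusted p = 0.088 with an estimated correlation, with a range of 1.5e-06 to 0.23. Its median was 0.51 with the correction and 0.63 otherwise. Of 10 MYC network genes 6 rose, including MYC itself and its antagonist MXD4, and 0 fell (camera adjusted p = 0.00038; adjusted p = 0.0068 with an estimated correlation). Of 6 measured dystrophin complex genes, 5 fell, among them SNTA1 as the target, SGCB and DAG1, and 0 rose (camera adjusted p = 0.00038; adjusted p = 0.038 with an estimated correlation). Without SNTA1 the 5 others had a camera adjusted p of 0.0097 and no longer passed with an estimated correlation, at an adjusted p = 0.25 with an estimated correlation, with a range of 0.00015 to 0.25. In the BCL2 family BBC3, which encodes PUMA, rose from 7.32 ± 0.630 to 18.8 ± 1.04 FPKM and BCL2L1 from 86.9 ± 1.98 to 153 ± 3.62 FPKM, while BCL2L2 fell from 18.3 ± 0.522 to 12.1 ± 0.716 FPKM (limma adjusted p = 1.7e-07, 6.0e-10 and 3.1e-07). Of the 9 measured pro-apoptotic members 4 rose, BBC3, BAX, BAK1 and PMAIP1, and 0 fell (camera adjusted p = 0.034; adjusted p = 0.40 with an estimated correlation). This call was also lost with correction for GC and length (camera adjusted p = 0.14), at a median of 0.02 in place of 0.12, with a range of 0.0082 to 0.40 over all alternatives. PMAIP1 lost its call without non-targeting replicate 1 (limma adjusted p = 0.061) and SNTA1 siRNA replicate 3 (0.052) and with scaling to the total outside short RNA (0.0505), with a range of 0.0013 to 0.061 over all alternatives.

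Ribosomal and MYC-repressed lists were called with SNTA1 siRNA too. Of 50 cytosolic ribosomal protein genes, 14 rose and 0 fell (camera adjusted p = 2.4e-07; adjusted p = 0.51 with an estimated correlation). Of 41 ribosome biogenesis genes 12 rose, RRP12 the most, and 1 fell (camera adjusted p = 0.00057; adjusted p = 0.40 with an estimated correlation). Of 13 genes reported as MYC-repressed 6 rose, with CDKN1A and BTG2, which are also p53 targets, leading, and 3 fell (camera adjusted p = 0.0029; adjusted p = 0.059 with an estimated correlation). The largest single rises beside GDF15 were those of the collagenase gene MMP1 (2.89 ± 0.348 to 20.2 ± 3.42 FPKM, SD, n = 4 each), LOC730755 (2.61 ± 0.627 to 17.3 ± 2.73) and the polyamine enzyme gene SAT1 (36.6 ± 2.15 to 144 ± 15.7), and SUN3, CEBPB and SNORD35B were also among the 10 largest. SNORD35B, a short RNA, lost its call without non-targeting replicate 2 (limma adjusted p = 0.054) and with mock in place of non-targeting siRNA (0.54), with a range of 0.00065 to 0.54 over all alternatives. The largest falls were those of LAMP1, an abundant lysosomal membrane protein (138 ± 7.47 to 37.5 ± 3.12 FPKM; log2 change -1.86 ± 0.07, limma adjusted p = 2.0e-13), CCNYL1 (10.4 ± 0.760 to 2.69 ± 0.431), BUB1B, GINS1, LMBRD1, CYB5A, BZW2, ZNF770, SELT and PRDX3. Of these, LAMP1, CCNYL1, GINS1, LMBRD1, CYB5A, BZW2, ZNF770 and PRDX3 carry the heptamers GCTAACT, CTAACTA or both in their 3' UTRs. BUB1B and SELT carry neither of them, but both carry CTAACTT. These heptamers are taken up below as possible seed matches of the siRNA. VIM, the intermediate filament gene of mesenchymal cells, fell from 9.77 ± 0.740 to 3.57 ± 0.480 FPKM.

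limma called 3120 of 10713 genes between SNTA1 and non-targeting siRNA, 1316 higher (42.2%) and 1804 lower. Of these, 86 had a log2(FPKM + 1) change of at least 1 in size, 36 higher and 50 lower. With libraries weighted by quality the count was 5507. It was 4375 without Myc siRNA replicate 4 in the common fit, a library that is not part of this comparison. Scaling each library to the total outside short RNA moved the share of higher calls to 25.7%. Quantile normalization and median ratio scaling moved it the other way, to 47.9% and 48.7%. All 4 libraries of one group lay above all 4 of the other in 39.7% of loci, against the 2.86% that chance gives. Camera called 12 of the 26 lists, and 8 of these also with an estimated correlation. The 14 others had camera adjusted p from 0.055 to 0.65. They were cholesterol and fatty acid synthesis (9 of 23 higher, 1 lower), glycolysis (4 of 20 higher, 0 lower), unfolded protein response (6 of 19 higher, 6 lower) and tandem-pore channels (1 of 3 higher, 0 lower). Next came death receptors, caspases and IAPs (6 of 21 higher, 4 lower), classical MYC-activated genes (7 of 37 higher, 5 lower), RNA interference genes (0 of 13 higher, 1 lower), anti-apoptotic BCL2 genes (2 of 5 higher, 1 lower) and lysosome and autophagy (9 of 27 higher, 5 lower). The last were hypoxia response (1 of 11 higher, 2 lower), epithelial markers (1 of 4 higher, 0 lower), interferon response (3 of 25 higher, 3 lower), mesenchymal markers (3 of 5 higher, 1 lower) and nucleotide and folate synthesis (5 of 24 higher, 8 lower). The cholesterol list passed without non-targeting replicate 1 (camera adjusted p = 0.028), SNTA1 siRNA replicate 1 (0.032) or SNTA1 siRNA replicate 2 (0.028), and with correction for GC and length (0.023), with a range of 0.023 to 0.44 over all alternatives. Adjusted over the list alone, 25 G1/S genes were lower, 13 ribosomal protein genes, 13 ribosome biogenesis genes and 7 histone genes were higher and 3 immediate early genes lower, the other called lists having equal counts.

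With KCNK1 siRNA SEPHS2, ACAT1 and the spindle checkpoint gene MAD2L1 were lower and genes of cholesterol synthesis higher. SEPHS2, which makes the selenium donor of selenoproteins, fell from 67.3 ± 1.22 to 8.32 ± 2.81 FPKM (SD, n = 4 each; log2 change -2.92 ± 0.14, limma adjusted p = 5.7e-12). ACAT1, a mitochondrial thiolase, fell from 56.7 ± 2.61 to 12.9 ± 0.857 FPKM (limma adjusted p = 1.7e-14) and MAD2L1 from 114 ± 7.36 to 40.6 ± 8.08 FPKM (log2 change -1.49 ± 0.12, limma adjusted p = 1.3e-08). The mitosis list as a whole, with 2 of 36 genes higher and 5 lower, was not called (camera adjusted p = 0.89). Of 23 measured genes of cholesterol and fatty acid synthesis, 12 rose and 0 fell, including INSIG1 (12.1 ± 0.827 to 18.9 ± 1.18 FPKM), MSMO1 and the regulator SREBF2, with a camera adjusted p of 2.4e-06 and an adjusted p = 0.080 with an estimated correlation. Of 41 ribosome biogenesis genes, 18 fell and 0 rose, NHP2 (140 ± 9.67 to 90.1 ± 9.50 FPKM), PES1 and NOP16 the most (camera adjusted p = 2.4e-06; adjusted p = 0.32 with an estimated correlation). EGR1 fell from 35.4 ± 3.44 to 12.8 ± 1.5 FPKM (log2 change -1.40 ± 0.09, limma adjusted p = 1.5e-09), and EGR3 and FOS were lower too, but the 24 immediate early genes had 6 higher and 8 lower and were not called as a list (camera adjusted p = 0.89).

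More lists were called with KCNK1 siRNA. Of 31 genes of the G1/S transition and DNA replication, 11 rose, with CCNE2, POLE, RRM2 and LIG1 leading, and 1 fell (camera adjusted p = 0.00020; adjusted p = 0.27 with an estimated correlation). Of 13 genes reported as MYC-repressed, 8 rose, including KLF6 and CDKN1B, and 0 fell (camera adjusted p = 0.00049; adjusted p = 0.080 with an estimated correlation). Of 11 hypoxia genes 5 rose and 1 fell (camera adjusted p = 0.015; adjusted p = 0.22 with an estimated correlation). Of 27 lysosome and autophagy genes 12 rose and 4 fell, ATP6V1A the most (camera adjusted p = 0.018; adjusted p = 0.57 with an estimated correlation). Classical MYC-activated genes were lower for 13 of 37 and higher for 2 (camera adjusted p = 0.038; adjusted p = 0.74 with an estimated correlation). That call was lost without non-targeting replicate 4 (camera adjusted p = 0.067), KCNK1 siRNA replicate 1 (0.064) or KCNK1 siRNA replicate 2 (0.052), with median ratio scaling (0.054) and with correction for GC and length (0.12), with a range of 0.0065 to 0.78 over all alternatives. The medians in the last 2 settings were -0.14 and -0.14, against -0.16 in the reported test. In the BCL2 family MCL1 fell from 338 ± 10 to 258 ± 26.0 FPKM (SD, n = 4 each; limma adjusted p = 0.00017), BCL2L1 was 79.9 ± 3.38 FPKM against 86.9 ± 1.98, and 0 of 9 pro-apoptotic members were called (camera adjusted p = 0.46). Of these, BBC3 and BAK1 passed as higher with only the 2 groups in the fit (limma adjusted p = 0.0088 and 0.011), with mock in place of non-targeting siRNA (0.029 and 0.0015), with libraries weighted by quality (0.0093 and 0.0047), with scaling to the total outside short RNA (0.030 and 0.016) and without Myc siRNA replicate 4 (0.020 and 0.028). BAK1 also passed with quantile normalization (0.011) and with correction for GC and length (0.0078). The ranges over all alternatives were 0.0088 to 0.59 for BBC3 and 0.0015 to 0.16 for BAK1. Outside short RNAs the largest rises were those of CALD1, an actin-binding protein (27.7 ± 5.41 to 106 ± 34.7 FPKM), KLF2 (9.20 ± 1.48 to 27.4 ± 6.39) and TMSB4X (47.9 ± 8.29 to 118 ± 15.6), followed by MYOF, HES4 and RHOB. SNORD57 and MIR3661 were higher by as much, but the FPKM of such short loci is uncertain. The call of SNORD57 was lost without non-targeting replicate 2 (limma adjusted p = 0.13) or 3 (0.18), without each KCNK1 siRNA replicate (0.079, 0.055, 0.14 and 0.073 for 1 to 4), with the robust variance model (0.060) and with mock in place of non-targeting siRNA (0.11), with a range of 0.0014 to 0.18 over all alternatives. That of MIR3661 was lost with mock (limma adjusted p = 0.073; range 0.00037 to 0.073). Further falls were those of ZNF252, KCNK1 itself, ATPAF1, RNF11, NGFRAP1, ARL2BP and ARRB2, at log2 changes of -1.82 to -1.45. ACAT1, MAD2L1, ATPAF1, NGFRAP1 and ARL2BP carry the heptamers CCTATGA, CCCTATG or both in their 3' UTRs, taken up below as possible seed matches. SEPHS2, KCNK1, RNF11 and ARRB2 carry neither, and ZNF252 had no annotated 3' UTR.

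limma called 2890 of 10713 genes between KCNK1 and non-targeting siRNA, 1202 higher and 1688 lower. Of these, 40 had a log2(FPKM + 1) change of at least 1 in size, 9 higher and 31 lower. With only these 2 groups in the fit the count was 4613, and with libraries weighted by quality 5206. It was 4292 without Myc siRNA replicate 4 in the common fit, a library that is not part of this comparison. The share of higher calls was 41.6%. It was 48.4% with quantile normalization, 47.0% with median ratio scaling and 47.2% with scaling to the total outside short RNA. All 4 libraries of one group lay above all 4 of the other in 39.1% of loci, against the 2.86% that chance gives. Camera called 7 of the 26 lists, and 0 of these with an estimated correlation. The other 19 had camera adjusted p from 0.053 to 0.99. Beside the mitosis, immediate early and pro-apoptotic lists they were interferon response (5 of 25 higher, 0 lower), tandem-pore channels (0 of 3 higher, 2 lower, with KCNK1 one of them), the dystrophin complex (3 of 6 higher, 0 lower), and anti-apoptotic BCL2 genes (0 of 5 higher, 3 lower). Next came RNA interference genes (2 of 13 higher, 0 lower), NF-kB genes (0 of 8 higher, 2 lower), epithelial markers (0 of 4 higher, 1 lower), histones (0 of 11 higher, 3 lower), ribosomal proteins (0 of 50 higher, 2 lower) and unfolded protein response (3 of 19 higher, 1 lower). The last were the MYC network (2 of 10 higher, 2 lower), p53 targets (1 of 27 higher, 7 lower), nucleotide and folate synthesis (4 of 24 higher, 7 lower), death receptors, caspases and IAPs (4 of 21 higher, 3 lower), glycolysis (4 of 20 higher, 2 lower) and mesenchymal markers (1 of 5 higher, 2 lower). The interferon list passed without non-targeting replicate 1 (camera adjusted p = 0.041) or 2 (0.029), KCNK1 siRNA replicate 3 (0.035) or 4 (0.034), or Myc siRNA replicate 4 (0.044), with only the 2 groups (0.043), with the replicate number as a block (0.044) and with correction for GC and length (0.027), with a range of 0.027 to 0.53 over all alternatives. The tandem-pore list passed without KCNK1 siRNA replicate 3 (camera adjusted p = 0.035), with a range of 0.035 to 0.42, and the anti-apoptotic list passed with a filter of 5 FPKM (0.037), with a range of 0.037 to 0.42. Adjusted over the list alone, the called lists had 22 ribosome biogenesis and 14 classical MYC-activated genes lower and 13 cholesterol synthesis, 13 G1/S and 7 hypoxia genes higher, the 2 remaining lists having equal counts.

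**Figure D2:**
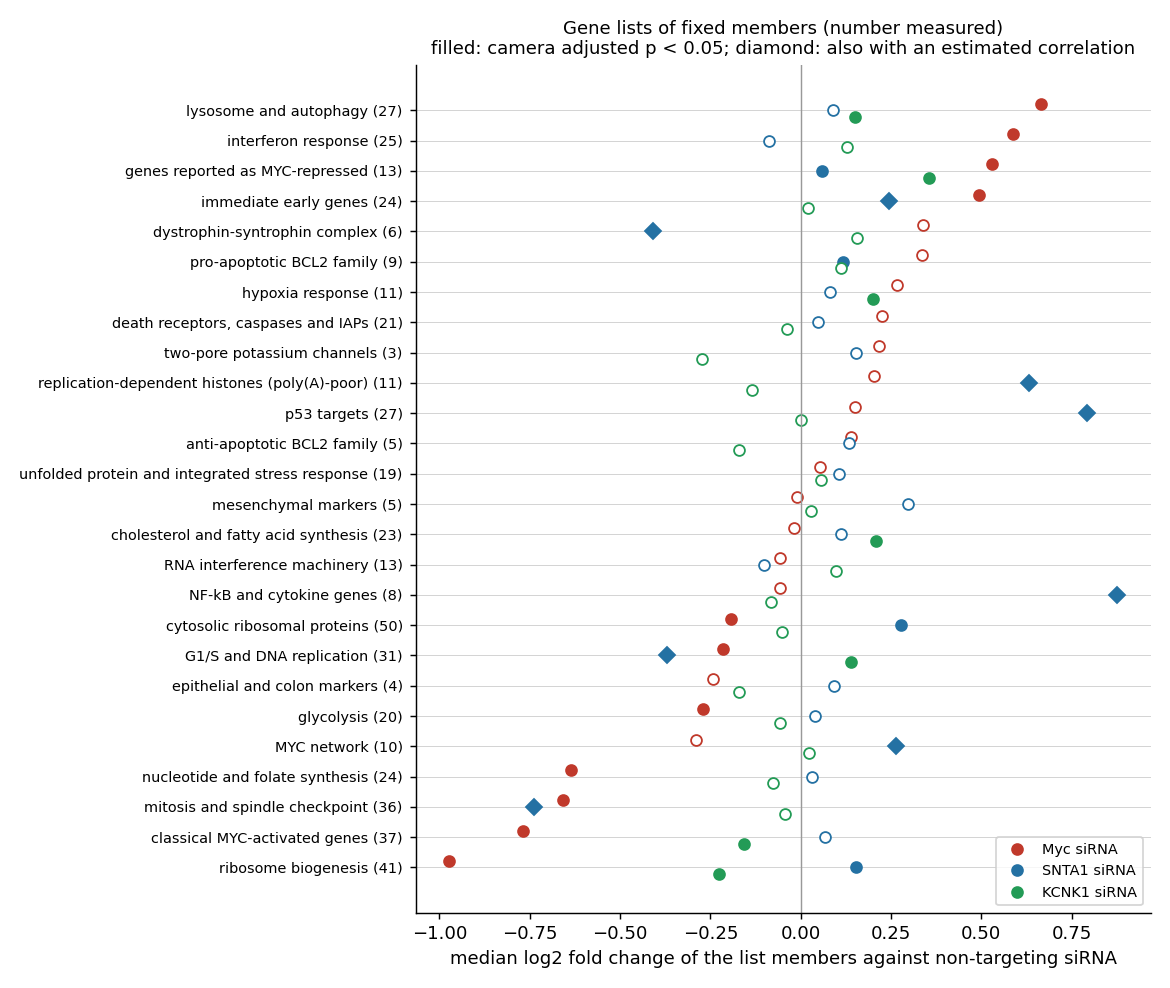
Median log2 fold change against non-targeting siRNA (horizontal axis) of the measured members of each gene list (vertical axis, number measured in parentheses) with Myc, SNTA1 and KCNK1 siRNA; filled symbols passed camera and diamonds also passed with an estimated correlation. With Myc siRNA the ribosome biogenesis list lay lowest, at -0.97, and with SNTA1 siRNA the mitosis list lay lowest, at -0.74, and p53 targets at 0.79.

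**Figure D3:**
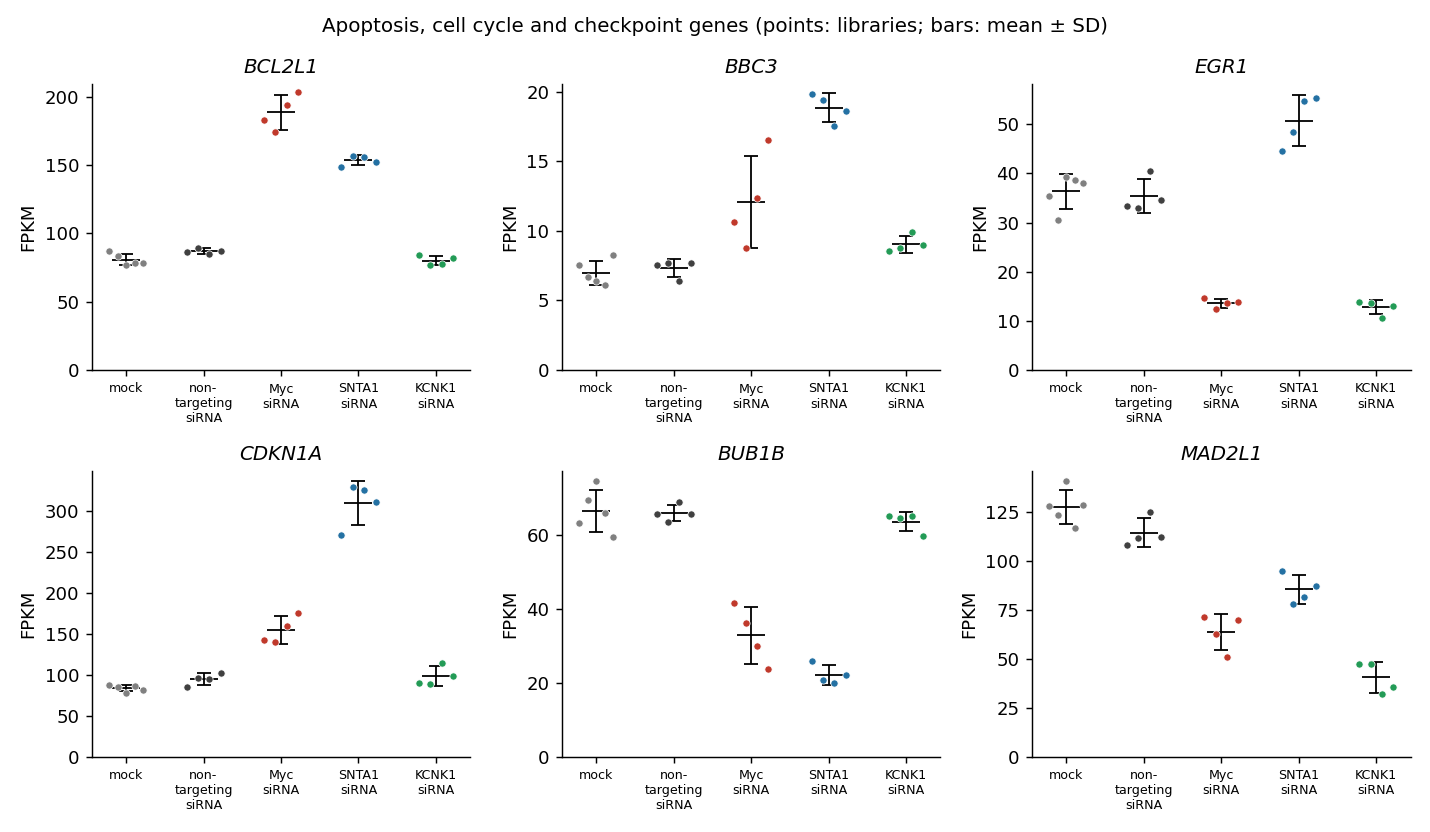
FPKM (vertical axis) of BCL2L1, BBC3, EGR1, CDKN1A, BUB1B and MAD2L1 in each library by transfection group (horizontal axis); points are libraries, and bars give the mean ± SD of 4 libraries, or 5 for mock. BCL2L1 was higher with Myc and SNTA1 siRNA, EGR1 was lower with Myc and KCNK1 siRNA, and MAD2L1 was lowest with KCNK1 siRNA, at 40.6 FPKM on average.

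Non-targeting siRNA and mock transfection gave the background of the other comparisons. MYC was 219 ± 8.31 FPKM (SD, n = 4) against 201 ± 11.1 (SD, n = 5), BCL2L1 86.9 ± 1.98 against 80.6 ± 4.14, CDKN1A 94.8 ± 6.89 against 83.8 ± 3.89 and EGR1 35.4 ± 3.44 against 36.4 ± 3.59. limma called 0 of 10713 genes, with 463 at an unadjusted p below 0.05, and weighting the libraries by their quality in limma gave 56. In 4.05% of loci the groups did not overlap, against the 1.59% that chance gives for 4 against 5. Camera called 0 of 26 lists. The lysosome and autophagy list, at a camera adjusted p of 0.11, passed without non-targeting replicate 3 (0.0084), mock replicate 2 (0.040) or mock replicate 4 (0.045), with a range of 0.0084 to 0.92 over all alternatives. With correction for GC and length the ribosome biogenesis (camera adjusted p = 0.035), mitosis (0.035) and epithelial (0.019) lists passed, with ranges of 0.035 to 0.99, 0.035 to 0.99 and 0.019 to 0.92.

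Direct comparisons between the siRNAs tested the differences themselves. MYC was higher with SNTA1 than with Myc siRNA (log2 difference 0.88 ± 0.07, limma adjusted p = 4.6e-10), while KCNK1 against Myc siRNA did not pass the test for MYC (169 ± 11.9 against 154 ± 9.70 FPKM, SD, n = 4 each; limma adjusted p = 0.088). It passed without Myc siRNA replicate 4 (limma adjusted p = 0.025) or KCNK1 siRNA replicate 2 (0.042), with quantile normalization (0.020), median ratio scaling (0.017) or scaling to the total outside short RNA (0.020), and with libraries weighted by quality (0.0091), with a range of 0.0091 to 0.26 over all alternatives. CAV1 was 1.85 ± 0.172 FPKM with SNTA1 and 37.3 ± 3.27 with Myc siRNA, and GPI 174 ± 5.38 against 27.5 ± 7.41 FPKM. GDF15 was 47.7 ± 7.23 FPKM with SNTA1 siRNA, 6.33 ± 1.27 with Myc siRNA and 4.25 ± 0.578 with KCNK1 siRNA, and its difference passed the test against both of these (limma adjusted p = 1.0e-12 and 4.7e-13). SEPHS2 was 8.32 ± 2.81 FPKM with KCNK1 siRNA against 70.5 ± 6.83 with Myc and 76.2 ± 3.41 with SNTA1 siRNA, and NGFRAP1 35.7 ± 5.86 with KCNK1 against 214 ± 55.9 with Myc siRNA. limma called 7017 genes between SNTA1 and Myc siRNA (42.5% higher with SNTA1), 6616 between KCNK1 and Myc siRNA (41.9% higher with KCNK1) and 5138 between KCNK1 and SNTA1 siRNA (49.9% higher with KCNK1). With quantile normalization the share was 52.0% for KCNK1 against Myc siRNA and 50.9% for SNTA1 against Myc siRNA. It was 66.7% for KCNK1 against SNTA1 siRNA with scaling to the total outside short RNA, which moved the median log2 difference of all genes by 0.11 in that comparison, to 0.11.

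The changes with KCNK1 siRNA overlapped most with those of Myc siRNA. Of the genes called in both, 865 were higher and 790 lower with both siRNAs, where independent lists would share 408 and 469, and 423 went opposite ways, against 908. For Myc and SNTA1 siRNA the counts were 600 and 633, against 447 and 501 for independent lists, and 893 went opposite ways, against 979. For SNTA1 and KCNK1 siRNA 530 genes went the same way, 291 of them lower, where independent lists would share 148 higher and 284 lower, and 494 went opposite ways, against 410. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.378 for Myc and KCNK1, 0.104 for Myc and SNTA1 and 0.0226 for SNTA1 and KCNK1. These comparisons share the non-targeting libraries, so 100 simulations of unchanged groups with a shared control were run. Each drew deviations of libraries from their group means, out of all 21 libraries and not only the controls. Myc siRNA replicate 4 could therefore enter. The simulations gave a mean r of 0.454 and 0 genes called in both, as unchanged groups leave few calls to share. The covariances were 0.0482, 0.0145 and 0.00161, where the simulations had a mean of 0.00704 and a highest value of 0.0425, with a highest r of 0.931. Only the covariance of Myc and KCNK1 lay above all the simulated ones. Myc siRNA replicate 4 could serve as a shared control in the simulations, which it never does in the data. The highest simulated value therefore cannot decide for the other pairs. With the controls split 2 and 2 the siRNAs shared none. Over 6 such splits r was 0.303 to 0.376 for Myc and KCNK1, and the shared calls numbered 892 to 943. For Myc and SNTA1 r was then 0.0587 to 0.102, with 710 to 785 shared calls. For SNTA1 and KCNK1 it was -0.0652 to 0.0187, with 211 to 231 shared calls. The r of Myc and SNTA1 was 0.052 without Myc siRNA replicate 4, and that of SNTA1 and KCNK1 lay between -0.0048 without KCNK1 siRNA replicate 4 and 0.054 without non-targeting replicate 4, and was -0.0030 without SNTA1 siRNA replicate 2. With all 3 siRNAs 771 genes were called, 196 higher and 149 lower with each, against 50.2 and 79.0 for independent lists. The 3 comparisons share the non-targeting libraries, so they are not independent. Neither simulations nor split controls were run for all 3 together, so a common response cannot be read from these counts. Among those higher with each were RHOB, PIP5KL1, CBLB, MT1L and HMOX1, the heme-degrading enzyme induced by oxidative stress (97.5 ± 23.8 FPKM with non-targeting, 417 ± 143 with Myc, 151 ± 30.3 with SNTA1 and 176 ± 48.0 with KCNK1 siRNA; SD, n = 4 each). HMOX1 lost its call with SNTA1 siRNA (limma adjusted p = 0.037) without non-targeting replicate 1 (0.14), 2 (0.051) or 3 (0.081) or SNTA1 siRNA replicate 2 (0.11), 3 (0.051) or 4 (0.11), with a range of 0.00016 to 0.14. Among those lower with each were SLC7A5, TUBA4A, ARHGAP11A, NIF3L1 and HMGN5, the last losing its call with KCNK1 siRNA without KCNK1 siRNA replicate 3 (limma adjusted p = 0.053; range 0.00033 to 0.053).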

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

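The tests of transcript length and GC and of a wrong label for Myc siRNA replicate 4, and those of shared controls for the seed matches, were chosen only after the results were seen. For 27 measures in 5 groups, 135 sets of libraries, the most extreme library's gap to the nearest other was divided by the range of the group. Chance makes about 1 in 20 such sets stand out, or 6.75 of them, and 11 did.

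Replicate 4 of the Myc siRNA stood out in 6 of the measures. Its gap as a share of the range was 0.8306 for the MIR4461 share (31.4% against 47.4% to 50.7%), 0.8305 for the short RNA share (36.5% against 52.3% to 55.5%), 0.9388 for the total outside short RNA (651464 against 505511 to 514449) and 0.9424 for the median FPKM (16.5 against 17.4 in each other library). It was 0.9511 for the SD of the deviation from the group (0.471 against 0.203 to 0.216) and 0.9769 for the correlation of that deviation with transcript length (-0.743 against 0.570 to 0.601).

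For this library, GC and transcript length together accounted for 62.25% of the variance of its deviation across loci, against 1.16% to 49.1% in the other 20 libraries. Each deviation was taken from the mean of the group's other libraries. The values of the other Myc libraries (33.0%, 49.1% and 31.9%) may therefore partly mirror replicate 4. Outside the Myc siRNA group the highest was 41.9%, in mock replicate 1 and KCNK1 siRNA replicate 2. A length and GC bias of Myc siRNA replicate 4 would give such a gap. A library from another group would show little of the change of the other Myc libraries, but its slope on their change was 0.9482, with 0.862 to 1.11 for the other 3 (SD 0.126), which argues against a wrong label. With that spread, a small share of cells without the Myc siRNA cannot be told apart from a pure sample at the same slope of 0.9482. A biological difference of this culture from the others was not tested.

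The remaining sets were single values. BBC3 was lowest in non-targeting replicate 3 (6.38 FPKM against 7.54 to 7.68, gap share 0.8875). PLAU was highest in KCNK1 siRNA replicate 3 (45.1 FPKM against 38.3 to 39.2, gap share 0.8662). BUB1B was lowest in KCNK1 siRNA replicate 4 (59.6 FPKM against 64.4 to 65.0, gap share 0.8907). ACAT1 was lowest in SNTA1 siRNA replicate 2 (53.2 FPKM against 58.4 to 58.6, gap share 0.971). The correlation of the deviation with transcript length was lowest in KCNK1 siRNA replicate 4 (-0.415 against 0.0961 to 0.163, gap share 0.8849).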

How the results depend on the processing

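The GC and length correction, array weights, scaling outside short RNA, leaving Myc siRNA replicate 4 out of the common fit, lists less the targeted gene and the authors' q-values were chosen after the data were seen. Knockdown of the 3 targeted genes kept its direction and call in all 62 alternatives, at log2 changes of -0.56 to -0.38 for MYC, -2.75 to -1.69 for SNTA1 and -2.06 to -1.63 for KCNK1. Of the gene counts 140 of the alternatives lay within 1.5 times the reported count and 11 did not. Tests of single lists gave the same call in 2082 alternatives, lost it in 86 and gained it in 20, and named genes did so in 8752, 302 and 28, with 0 reversed.

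With an estimated correlation 0 lists were called for Myc and 0 for KCNK1 siRNA. With that and the GC and length correction the counts were 0 (Myc), 5 (SNTA1) and 0 (KCNK1), and without Myc siRNA replicate 4 in the fit 0, 6 and 0. The GC and length correction alone gave 3 lists between non-targeting siRNA and mock, and leaving out 1 library there gave 0 to 1. With an absolute log2 change of at least 1 the counts of genes were 535 (Myc), 86 (SNTA1), 40 (KCNK1), 771 (SNTA1 against Myc), 402 (KCNK1 against Myc) and 195 (KCNK1 against SNTA1), fewer by construction. With only the 2 groups KCNK1 siRNA had 4613 genes. Array weights gave 5507 (SNTA1), 5206 (KCNK1) and 56 (non-targeting against mock), and the authors' q-values 4125 for Myc siRNA. Without Myc siRNA replicate 4, which enters neither comparison, the counts were 4375 (SNTA1) and 4292 (KCNK1), against 3120 and 2890. The median log2 changes moved by 0.0 there, so those counts rose through the spread that the groups share in the fit. The cause of the other shifts was not tested.

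With controls split 2 and 2, so that fewer libraries entered each test, shared calls averaged 741.17 (Myc and SNTA1), 922.5 (Myc and KCNK1) and 216.5 (SNTA1 and KCNK1), and r for SNTA1 and KCNK1 was -0.018318. Leaving out libraries gave an r of 0.052161 to 0.12624 for Myc and SNTA1 and -0.0047761 to 0.053917 for SNTA1 and KCNK1. Gene counts ranged from 6188 to 7385 (Myc), 2527 to 4375 (SNTA1), 1956 to 4292 (KCNK1) and 0 to 0 (non-targeting against mock), with each highest count for an siRNA reached without Myc siRNA replicate 4.

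With a replicate block limma called 6769 (Myc), 3282 (SNTA1), 3076 (KCNK1) and 0 (non-targeting against mock) genes. Libraries sharing a number were correlated in their deviations by -0.386 to 0.561, and 6 of 21 had their best match in another group under the same number. The robust variance model was not run for gene lists, since camera has no such option. Depth is unknown, so limits from it are not given.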

Other observations

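The genes of the first paragraph and the tests of shared controls were chosen only after the values were seen. Some genes were at 1 FPKM or more in every library of a group only with Myc siRNA. The deposited table holds no locus with a group's libraries on both sides of 1 FPKM, so the number of such loci depends on its filter. Loci found in that way only with SNTA1 siRNA numbered 2, and 0 for non-targeting siRNA, mock or KCNK1 siRNA. With Myc siRNA there were 62. Their median was 1.60 FPKM there against 0.504 FPKM with non-targeting siRNA, a direction fixed by the choice of loci. They included LDHD, which oxidizes D-lactate (3.66 ± 0.544 FPKM against 0.301 ± 0.0968, SD, n = 4 each), the fatty acid hydroxylase CYP2U1 (3.09 ± 0.370 against 0.713 ± 0.0604), the keratin KRT81 (2.81 ± 0.923 against 0.0960 ± 0.0588), the complement protease C1R (2.75 ± 0.397 against 0.270 ± 0.113), the ganglioside synthase ST3GAL5 (2.21 ± 0.404 against 0.304 ± 0.0782) and TIMP2, an inhibitor of matrix proteases (2.45 ± 0.636 against 0.552 ± 0.0675). How many reads lie behind levels near 1 FPKM is unknown.

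An siRNA can repress other transcripts through matches to its seed in 3' UTRs, and for the genes lower with SNTA1 siRNA such matches were searched as a hypothesis over 16140 heptamers. GCTAACT, found in 622 genes, had the most negative z, -14.37, and ATTTATT the most positive, 7.16, where 100 shuffles reached 4.70 in size and the most negative z of non-targeting siRNA against mock was -6.73. GCTAACT or CTAACTA was carried by 342 of 1745 genes called lower (19.6%), against 10.2% of all genes. Among called genes lower by at least 1 in log2(FPKM + 1) it was 22 of 49 (44.9%). The heptamers were chosen on the same changes, so these shares are no separate support, and they are not adjusted for 3' UTR length. Chosen in each part of the genes, GCTAACT ranked 1 in the other part, at z of -9.65 and -10.66. The z of GCTAACT was 11.01 for KCNK1 against SNTA1 siRNA, where no non-targeting library enters, which argues against the shared controls as its source, so off-target repression of carriers such as LAMP1, GINS1, CYB5A, BCL2L2, SGCB and ARHGAP11A may account for part of the fall, while the carriers PIP5KL1, RPS19 and SNAI1 were higher, at log2 changes of 0.62, 0.39 and 0.32. For mitosis genes 32 of the 35 members without GCTAACT or CTAACTA were also called lower. BUB1B among these carries CTAACTT (z -6.73). In all, 6 heptamers had a z below -6, and carriers of TGCTAAC (-7.74), CCAATCT (-6.61) and CTAACTG (-6.44) were not set aside either. The 35 members are thus not shown to be free of seed matches. The siRNA sequences are not given in the sources used here.

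KCNK1 siRNA gave the same kind of result with another sequence. CCTATGA, in 700 genes, had a z of -14.81, and 321 of 1577 genes called lower (20.4%) carried it or CCCTATG, against 10.6% of all genes. Among called genes lower by at least 1 in log2(FPKM + 1) it was 17 of 30 (56.7%). These shares too come from the changes used to choose the heptamers. CCCTATG, chosen in 1 part of the genes, ranked 2 in the other (z -10.46), and CCTATGA, chosen in the other part, ranked 2 in the first (z -8.13). The z of CCTATGA for KCNK1 against SNTA1 siRNA was -10.45, again without non-targeting libraries. The lower MAD2L1, ACAT1, MYC, ARHGAP11A and HMGN5 with this siRNA, which carry 1 of these heptamers, may therefore be off-target effects. SEPHS2, with the largest fall, and KCNK1 itself carry neither, while the carriers CBLB and INSIG1 were higher, at log2 changes of 0.92 and 0.60. For Myc siRNA the most negative z was -4.721, close to the 4.70 of the shuffles and smaller in size than the -6.73 between the controls, and the heptamers chosen in each part of the genes ranked 7317 and 3397 in the other, so a seed effect cannot be told apart from chance there.

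Other splits of the same libraries were used to ask whether chance could give as many calls. For Myc against non-targeting siRNA 1 of 35 splits, the real one, gave as many as 6617, and the highest other gave 3382, when Myc siRNA replicate 4 was exchanged with non-targeting replicate 1. For SNTA1 siRNA it was 1 of 35 (3120, highest other 0) and for KCNK1 siRNA 1 of 35 (2890, highest other 1). Between siRNAs it was 1 of 35 for SNTA1 against Myc (7017, highest other 3860, with Myc siRNA replicate 4 exchanged), 1 of 35 for KCNK1 against Myc (6616, highest other 2946, with the same library exchanged) and 1 of 35 for KCNK1 against SNTA1 (5138, highest other 2). In each of these 6 comparisons only the real grouping gave as many calls. A share of 1 of 35 is the smallest that these splits can give. In other splits a true difference adds to the spread within groups, which lowers their counts. The splits do not tell an effect of the siRNA from another difference between the groups. For non-targeting siRNA against mock any split matches the real count of 0, here 100 of 100, so the splits cannot tell there.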
